A study of Mus musculus with 6 samples.

How the data were processed

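RNA of 6 mouse bone marrow samples was analysed: 3 presort samples of whole marrow and 3 samples sorted for GFP driven by a renin transgene, each pair from 1 pool of 4 to 5 mice. Per the labels' protocols, RNA was extracted with Trizol, reverse transcribed, amplified and biotin-labelled by in vitro transcription from the 3' end with the Affymetrix 3' IVT Express kit. The deposited values are intensities on a linear scale, from 9.71 to 38492.08 on every array, which the authors made with RMA, per the submitters' processing notes; the version of RMA and the scan settings were not given in the sources used here. The sorted values of the 6 arrays agreed to within 0.181% of their mean, so the arrays share 1 distribution as quantile normalization leaves it, and a change in the total RNA per cell leaves no trace in them. The median intensity was 66.0 on each array. Because labelling starts at the 3' end of transcripts, degraded RNA or a short amplification lowers 5' probe sets more than 3' ones, and the beta-actin and Gapdh control probe sets were compared for this reason.

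Log2 of the deposited intensities was taken first, with no pseudocount. Of 45101 probe sets, 64 were control probe sets, 34945 carried 1 gene symbol and were used, 932 carried several and were named by none, and 9160 had no symbol here. The symbols come from the platform's annotation, of which 34741 single-symbol probe sets had their Entrez number in the reference gene table and 0 symbols were updated. For the 9010 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays stood for the gene, and 1588 genes were read by a probe set whose name ends in _x_at or _s_at and which can match several transcripts. No genome coordinates are given, since no genome build was used here. The renin gene itself is not reported here, so the sort was not checked against it. No pair of arrays shared more than 68 equal values, so no array is a copy of another.

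Sorted and presort samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom before moderation, two-sided), with Benjamini-Hochberg adjustment over 18193 genes and a threshold of 0.05; the count of larger changes asked for 2-fold besides. No dim genes were filtered out. Gene lists were tested with limma's camera with its preset correlation of 0.01 between genes, adjusted over 39 lists with at least 5 measured members, with the correlation estimated per list and limma's fry beside it. fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Of 914 genes in the lists 809 were measured, and 65 genes stand in more than 1 list. With the preset correlation 5 lists were higher and 24 lower, and with an estimated correlation 0 lists passed (camera, lowest adjusted p = 0.258; 2 lists had an unadjusted p under 0.05), while fry passed 28 of the 29 called lists in the same direction. The median, mean and test of a list differed in sign for 4 lists that were not called. The 3' to 5' differences were compared with a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

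The groups, the test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those said below to be chosen later. By that rule the text names each measured member of the renin-angiotensin list, the 12 largest rises and the 12 largest falls among called genes with 1 sign in all 3 pools (passing over unnamed transcripts), up to 4 members of a list with the largest called differences, and the 2 members of a cell type list with the highest mean; genes named outside it are said to be so. The design foresaw taking log2 first if the table was linear, and it was.

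Presort and sorted samples of one number come from 1 pool, per the labels, so the numbers pair the samples. The deviations of same-numbered samples from their group means correlated across genes at 0.39, 0.20 and -0.03 in pools 1, 2 and 3. The fit with the replicate number as a block is an alternative. Others fixed with it were leaving out each array or pool, the dimmest genes (33.3%), quantile normalization again, median centring, the mean of a gene's probe sets, no _x_at or _s_at probe sets, an intensity trend with a robust prior, array weights, limma's treat, camera on ranks, lists without shared genes, and no erythroid and heme genes. A covariate for the beta-actin 3' to 5' difference, fry, and quantile normalization over the named genes were chosen after seeing the data.

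The steps were tested on simulated data for the sorted against presort comparison, with 18193 genes of the real means and spreads, of which 200 were changed. Of changes of 1 on the log2 scale 65% were recovered and of changes of 2 on that scale 97%, with 5 false calls. Of the lists, camera called 3 of 3 shifted and 0 of 31 unshifted ones. The simulated genes were independent of each other, unlike real genes. The changed genes were also a far smaller share than the 32.6% of genes called in the data, so these rates need not carry over.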

Results

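Gene expression was measured in mouse bone marrow before and after sorting for green fluorescent protein (GFP) that a renin transgene drives. Marrow flushed from femurs of 4 to 5 adult mice of both sexes, 3 to 6 months old, was pooled on each of 3 sorting days. A part of each pool was kept unsorted (presort, n = 3) and the rest was sorted for GFP (sorted, n = 3), so that each presort array has a sorted partner from the same pool. The sort gates removed erythrocytes and debris by scatter, kept single cells, and had a lower GFP limit that let in 0.1% of cells from animals without the transgene. Each of the 6 samples was read on 1 Affymetrix 3' expression array, and 18193 named genes were compared. The number of arrays limits the precision of every value below, and without detection calls the changes of dim genes are understated on this intensity scale. Arrays of one group resembled each other more than arrays of different groups: correlations across genes, which are not independent replicates, were 0.992 to 0.996 within presort, 0.986 to 0.992 within sorted and 0.922 to 0.948 between the groups.

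The sorted samples had more RNA of B lineage genes and less of erythroid, granulocyte, monocyte, macrophage and cell division genes than whole marrow from the same pools. Of the B cell list, 22 of 23 measured members rose, with a median difference of 2.19 on the log2 scale (4.57-fold), and of the list of mitosis genes all 29 measured members fell, with a median of -2.58. Over all genes, 2629 were higher and 3296 lower in sorted samples (limma, Benjamini-Hochberg adjusted p under 0.05), which is 32.6% of the genes tested, and 7283 had an unadjusted p under 0.05. At least 2-fold changes were found for 1056 higher and 1872 lower genes. The sign was the same in all 3 pools for 5920 of the 5925 called genes. These genes were called on the same arrays, so this agreement is largely set by the call and is no separate replication. The sorted samples differed from presort in RNA quality too: the 3' probe set of beta-actin exceeded its 5' probe set by 0.96 ± 0.15 (SD, log2, n = 3) in presort and by 2.05 ± 0.98 (n = 3) in sorted samples. For Gapdh these differences were 1.78 ± 0.19 and 2.80 ± 0.91. Both gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 arrays allow. Sorted replicate 1 stood apart, at 3.17 for beta-actin and 3.84 for Gapdh, and without it 2608 genes were higher and 3256 lower. Leaving out pool 3 brought the higher genes down to 1544. With each array centred on its median over genes, 66.7% of the called genes were higher in sorted samples, against 44.4% as deposited, and the median of all genes moved from -0.0021 to 0.23, so that values nearer to 0 than this shift have no settled sign.

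**Figure D1:**
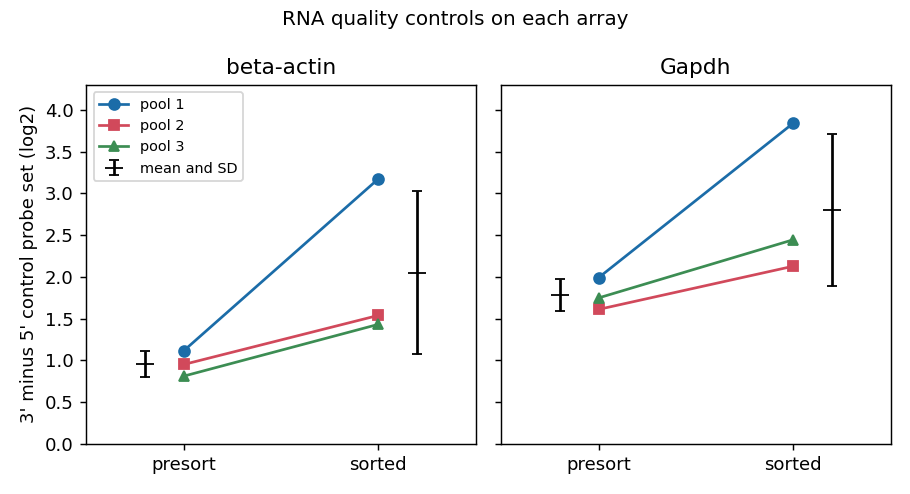
Difference between the 3' and 5' control probe sets of beta-actin and Gapdh (log2, vertical axis) on each presort and sorted array, with lines joining the arrays of one pool and black bars for the mean and SD (n = 3). Sorted replicate 1 lies at 3.17 and 3.84, above the other sorted arrays, which lie between 1.43 and 2.44.

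The 12 named genes with the largest rises included transcription factors of the immediate early class, lymphocyte surface proteins and signalling proteins. Fosb, a component of the AP-1 transcription factor, rose by 5.63 ± 1.08 (SE, log2; 49.5-fold; limma adjusted p = 0.00461), and Jun, another AP-1 component, by 4.19 ± 0.98 (adjusted p = 0.0122). Both varied between the presort arrays, with Fosb at 8.79, 5.35 and 4.51 and Jun at 10.37, 8.20 and 5.84 in presort replicates 1, 2 and 3. The call of Fosb was lost without pool 3 (adjusted p = 0.0588) and that of Jun without pool 2 (0.0878), and without pool 3 the rise of Jun was 2.75. Sertad4 rose from 6.24 ± 0.68 to 10.99 ± 0.04 (SD, log2, n = 3 each), and Cd69, an early activation antigen of lymphocytes, rose by 4.64 ± 0.25 (SE). Irs1, the insulin receptor substrate, rose by 4.41, Myzap by 4.07, Klhl14 by 3.94, the collagen chain gene Col5a3 by 3.90 and Ly6d, a surface protein of B lineage progenitors, by 3.82. Zbtb10 and Plk2, a polo-like kinase, each rose by 3.82, and Cth, the enzyme cystathionine gamma-lyase, by 3.73. Of these 12 genes the adjusted p ranged from 1.13e-05 for Col5a3 to 0.0122 for Jun, and 1 unnamed transcript was passed over among the rises. With the mean of their probe sets the rise was 2.06 for Col5a3, 1.84 for Zbtb10 and 1.95 for Plk2.

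The 12 named genes with the largest falls included genes of myeloid cells and of neutrophil granules. Arg2, the mitochondrial arginase, fell by 4.00 ± 0.31 (SE, log2, limma adjusted p = 4.97e-05), Itgam, the integrin CD11b chain of myeloid cells, fell by 3.97 ± 0.27, and Clec5a, a myeloid lectin receptor, fell by 3.97 ± 0.36. The aldehyde dehydrogenase gene Aldh1a7 stood at -3.93, Pla2g7 at -3.92, the transporter gene Slc6a20a at -3.90 and Hnmt, which methylates histamine, at -3.90. Chil1, a chitinase-like protein of neutrophil granules, stood at -3.89, H2-Q10 at -3.88, Ceacam10 at -3.86, Hacd4 at -3.85 and Cracd at -3.84. The adjusted p of these 12 falls ranged from 1.13e-05 for Slc6a20a to 0.000313 for Chil1. With the mean of their probe sets Ceacam10 stood at -2.39 and Cracd at -0.74.

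B lineage genes were the group with the highest list medians. In the B cell list, 22 of 23 measured genes rose, also when adjusted over the list alone, and none fell (camera adjusted p = 1.84e-13; adjusted p = 0.258 with an estimated correlation). Ebf1, a transcription factor that commits progenitors to the B lineage, rose from 9.45 to 12.51 (8.32-fold, limma adjusted p = 0.000117). Cd72 rose by 2.69 ± 0.20 (SE), Cd79b, a signalling chain of the B cell receptor, by 2.57 ± 0.25 and the kinase gene Blk by 2.50 ± 0.23. Ighm, the heavy chain of immunoglobulin M, rose by 0.55 at its brightest probe set and fell by 1.21 when all its probe sets were averaged. That brightest probe set lay near the top of the scale in both groups, at means of 14.38 in presort and 14.93 in sorted samples. The Ighm call was lost without pool 2 or pool 3 (limma adjusted p of 0.0644 and 0.0609), and without _x_at and _s_at probe sets it rose by 1.12. The list's median was 1.78 in pool 1, whose sorted array had the highest 3' to 5' differences, 2.27 in pool 2 and 2.61 in pool 3. Over this list presort replicate 1 exceeded presort replicates 2 and 3 by a mean of 0.70 ± 0.08 (SE over genes), which makes the pool 1 difference smaller.

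Of the B cell progenitor list, 14 of 18 measured members rose and 2 fell (median 1.47, camera adjusted p = 4.08e-05; adjusted p = 0.271 with an estimated correlation). Adjusted over the list alone, 14 rose and 4 fell. Rag1, a subunit of the recombinase that assembles antigen receptor genes, rose by 2.75 ± 0.16 (SE, 6.74-fold), Sox4 by 2.72 ± 0.33 (1.70 with the mean of its probe sets) and the interleukin receptor gene Il7r by 2.34 ± 0.25, and Bach2 and Smarca4, the members with the highest mean, by 2.22 and 1.22. The 2 members that fell, named after their values were seen, were Erg at -1.44 and Igll1, part of the surrogate light chain of the pre-B cell receptor, at -0.84. In pool 3 the difference of Igll1 was 0.00. Of the antigen presentation genes of the MHC class II list, 8 of 10 rose, 9 when adjusted over the list alone (median 1.01, camera adjusted p = 8.15e-05; adjusted p = 0.258 with an estimated correlation), led by H2-Ob at 2.09 and Cd74, the invariant chain, at 1.43.

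The plasma cell list shifted less and not in one direction: 6 of 13 members rose and 1 fell, with the same counts when adjusted over the list alone (median 0.41, camera adjusted p = 0.0290; adjusted p = 0.258 with an estimated correlation). The transcription factor gene Irf4 rose by 2.80, the syndecan gene Sdc1 by 2.53 (1.56 with the mean of its probe sets) and Prdm1 by 1.62, while Jchain, which joins immunoglobulin polymers, stood at -2.51. Xbp1 did not pass at -0.02. Sec11c, another bright member, rose by 0.85, a call lost without pool 2 (limma adjusted p = 0.0580) and with the beta-actin 3' to 5' covariate (0.47 ± 0.15, SE; 0.0603), while the mean of its probe sets rose by 1.96. The list's call was lost without sorted replicate 2 (camera adjusted p = 0.0642) and without pool 2 (0.0543). It was also lost with the mean of probe sets (median 0.22, 0.129), with each array centred on its median (median 0.63, 0.0900) and with quantile normalization over genes (0.0502). Over all alternatives its adjusted p ran from 0.00437, given by fry, to 0.258, given by camera with an estimated correlation. Without genes of more than 1 list its median was 0.67.

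**Figure D2:**
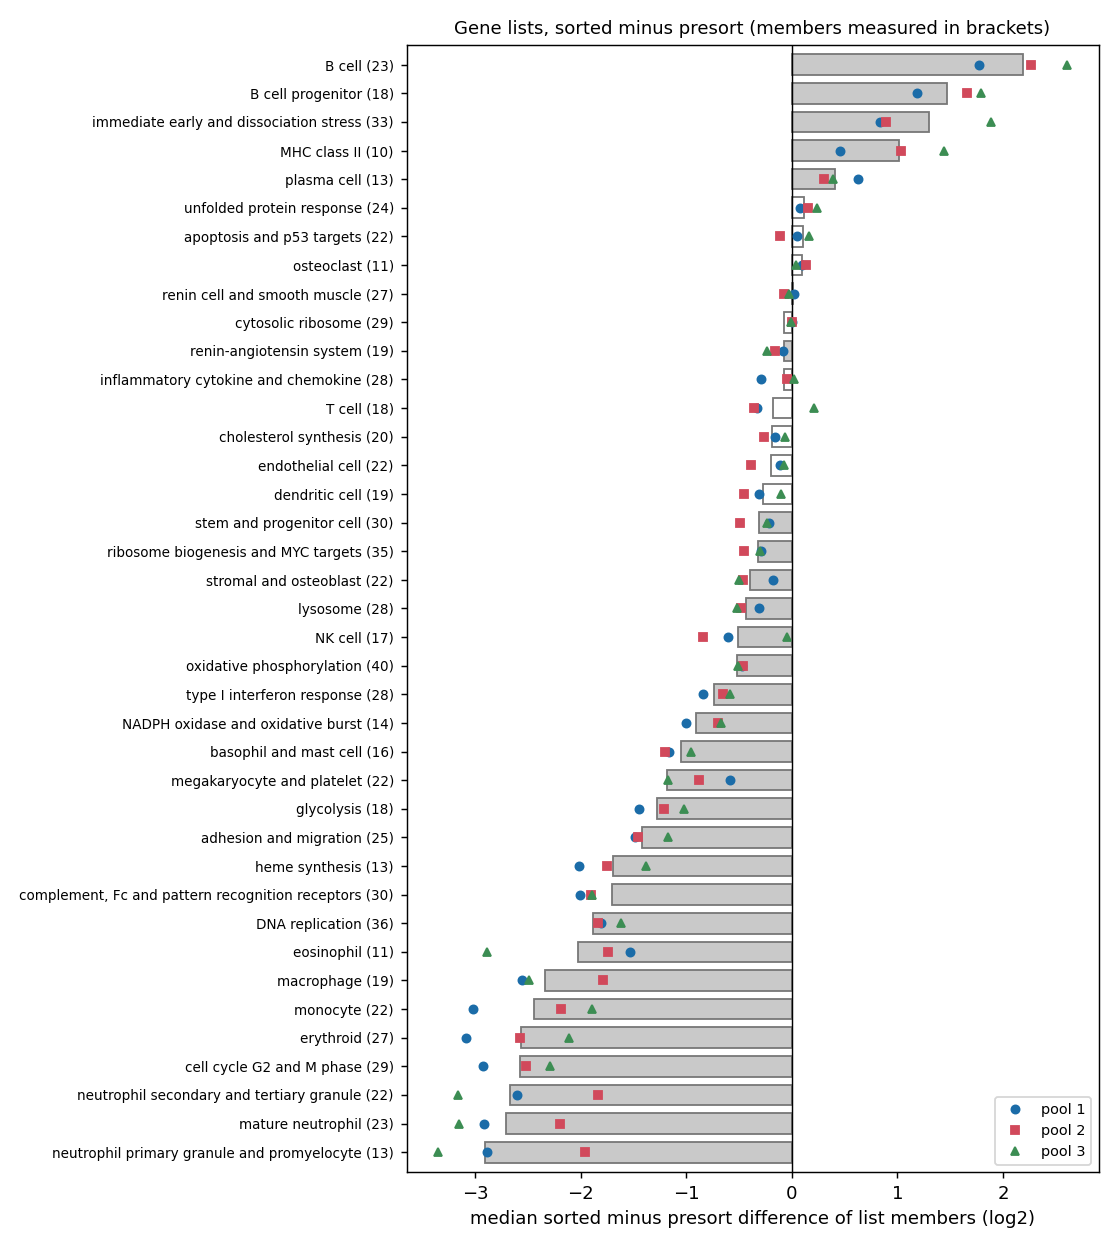
Median sorted minus presort difference (log2, horizontal axis) of each of the 39 gene lists, with the members measured in brackets, where bars give the median of the fitted differences (grey where the camera adjusted p was under 0.05, white otherwise) and symbols the median within each pool. B cell genes lie highest, at 2.19, and neutrophil primary granule genes lowest, at -2.91.

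Erythroid genes were lower in every pool. The sort gates removed erythrocytes by scatter and presort samples were unsorted, so this fall cannot be credited to the GFP gate alone. Of 27 measured members 26 fell and none rose, also when adjusted over the list alone (median -2.57, camera adjusted p = 1.45e-14; adjusted p = 0.258 with an estimated correlation). Car1, a carbonic anhydrase of red cells, stood at -3.65 ± 0.35 (SE), Icam4 at -3.40, the transcription factor gene Nfe2 at -3.35 and the water channel gene Aqp1 at -3.30. The members with the highest mean, Car2 and the mitochondrial iron importer gene Slc25a37, changed less, at -1.55 and -0.92. Of the heme synthesis list, 12 of 13 fell, and all 13 when adjusted over the list alone (median -1.70, camera adjusted p = 2.68e-08; adjusted p = 0.258 with an estimated correlation), with Tspo2 at -2.90 and Abcb10 at -2.31. The erythroid median was -3.08 in pool 1, where the 3' to 5' difference of the sorted array was highest, -2.57 in pool 2 and -2.11 in pool 3.

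Neutrophil genes of every stage were lower. Of the primary granule list 12 of 13 members fell (median -2.91, camera adjusted p = 5.49e-08), of the secondary and tertiary granule list 22 of 22 (median -2.67, 2.56e-12) and of the mature neutrophil list 20 of 23 (median -2.71, 3.47e-10). Each of these lists had an adjusted p = 0.258 with an estimated correlation. Adjusted over the list alone the counts of falls were 12, 22 and 20, with 1 rise in the mature neutrophil list. The serine protease gene Elane stood at -3.41, Cst7 at -3.37 and Ms4a3 at -3.33, and the brightest primary granule members, Mpo (myeloperoxidase) and Serpinb1a, at -2.11 and -1.15. Among the later granule genes, Pglyrp1 stood at -3.57 and the gelatinase gene Mmp9 at -3.49 ± 0.22 (SE). The members with the highest mean, Ngp and S100a8, lay near the top of the scale in both groups and stood at -0.69 and -0.81. The S100a8 call was lost without presort replicate 2, presort replicate 3, sorted replicate 3, pool 1 or pool 3, with adjusted p from 0.0545 to 0.155, and the Ngp call without pool 3 (0.0984). With the beta-actin 3' to 5' covariate both missed, Ngp at -0.56 ± 0.19 (SE; 0.0727) and S100a8 at -0.68 ± 0.28 (0.132), as S100a8 did with median centring (0.0545) and quantile normalization over genes (0.0891). Of the mature neutrophil genes, Stfa3 stood at -3.71, Clec4e at -3.44 and Csf3r, the granulocyte colony-stimulating factor receptor, at -3.43, with the bright receptor gene Fpr2 at -2.98 and Slfn4 at -2.96. The differences were smallest in pool 2, with list medians of -1.96, -1.83 and -2.20, against -3.35, -3.17 and -3.15 in pool 3.

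**Figure D3:**
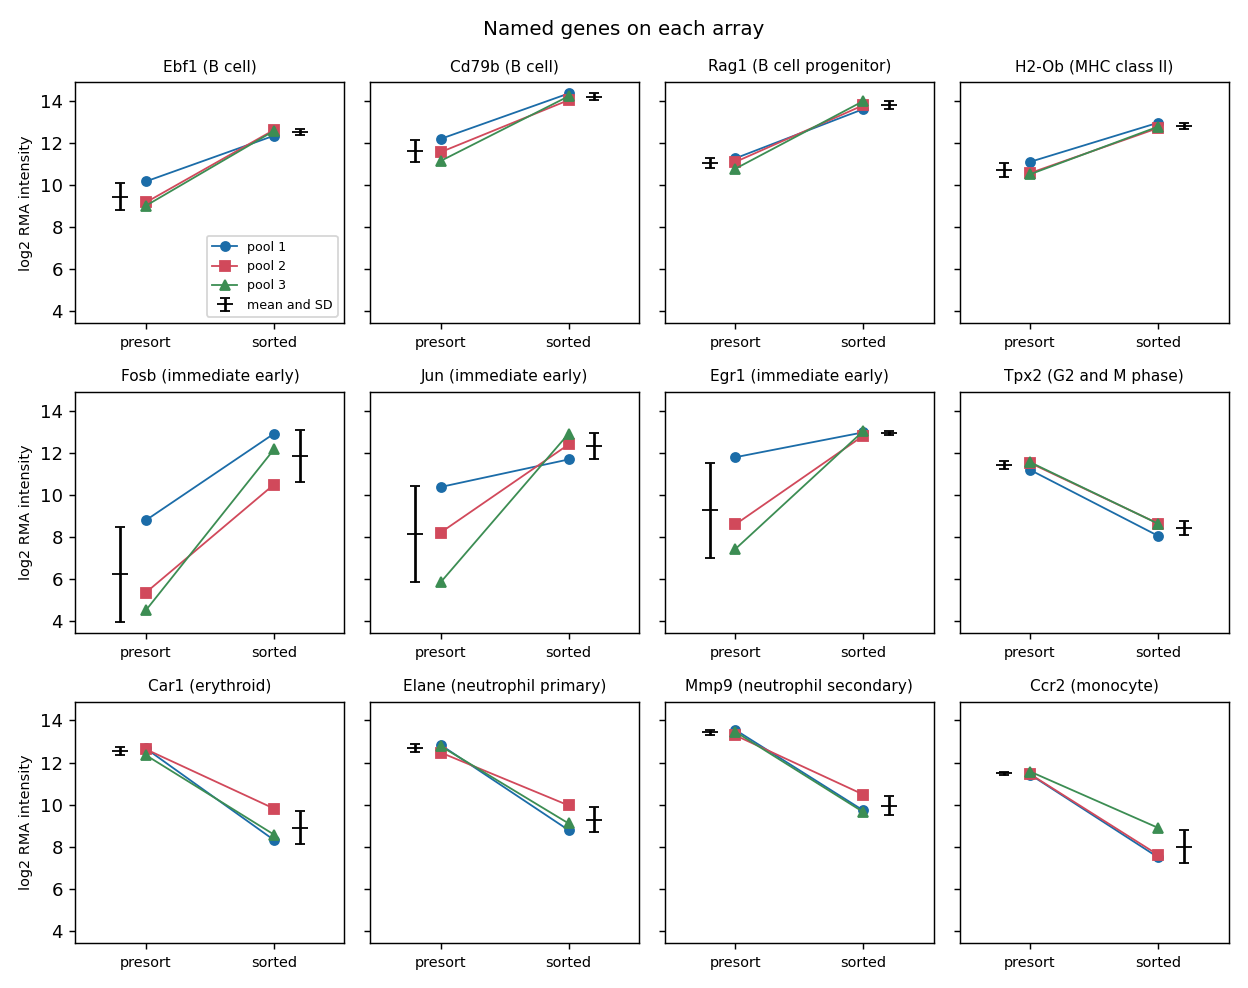
RMA intensity (log2, vertical axis) of 12 named genes on each array, with lines joining the presort and sorted arrays of one pool and black bars for the mean and SD (n = 3). Ebf1 and Cd79b lie higher in every sorted array, Car1, Elane, Mmp9 and Ccr2 lower, and the presort arrays of Fosb spread from 4.51 to 8.79.

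Most eosinophil and basophil genes fell as well. In the eosinophil list 7 of 11 members fell, also when adjusted over the list alone (median -2.02, camera adjusted p = 0.00164; adjusted p = 0.258 with an estimated correlation), with the peroxidase gene Epx at -3.68 and Alox15 at -3.42. Prg2, which encodes major basic protein, stood at -3.35 ± 0.93 (SE), and its call was lost without presort replicate 2, presort replicate 3, sorted replicate 3 or pool 3 (adjusted p from 0.0552 to 0.152). It was also lost with the beta-actin 3' to 5' covariate, where the fall shrank to -1.13 ± 0.59 (0.218), and with an intensity trend in the limma prior (0.0853), and without sorted replicate 1 it was called at -2.20. Cd24a, the brightest member, did not pass at -0.10. In the basophil and mast cell list 10 of 16 fell, also when adjusted over the list alone (median -1.05, camera adjusted p = 9.06e-05; adjusted p = 0.271 with an estimated correlation), with the basophil protease gene Mcpt8 at -3.38, the receptor kinase gene Kit at -3.28 (-1.83 with the mean of its probe sets) and Hdc, the histamine-forming enzyme, at -2.57. Without dim genes the median of this list was -2.55.

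Monocyte and macrophage genes were mostly lower. In the monocyte list 16 of 22 fell and 3 rose, and 4 rose when adjusted over the list alone (median -2.44, -1.41 with the mean of probe sets, camera adjusted p = 5.62e-05; adjusted p = 0.258 with an estimated correlation). The chemokine receptor gene Ccr2 stood at -3.48, Treml4 at -3.31 and Ccl9 at -3.08, whereas the bright member Ctss did not pass at 0.03. The 3 risers were Irf8 at 0.89 and, named after their values were seen, Klf4 at 2.10 and Nr4a1 at 1.73, of which Klf4 and Nr4a1 also belong to the immediate early list. The Irf8 call was lost without any of presort replicates 2 and 3, sorted replicates 1 and 3, or pool 3 (adjusted p from 0.0634 to 0.205), and with the beta-actin 3' to 5' covariate (0.54 ± 0.29, SE; 0.237). In the macrophage list 17 of 19 fell, also when adjusted over the list alone (median -2.34, camera adjusted p = 1.94e-08; adjusted p = 0.258 with an estimated correlation), with the complement gene C1qc at -3.09, the receptor kinase gene Axl at -3.02 (-1.55 with the mean of its probe sets) and the hemoglobin scavenger receptor gene Cd163 at -2.98. The bright members Ctsb and Slc40a1, the iron exporter, stood at -1.19 and -2.52, and Ctsb at -0.69 with the beta-actin 3' to 5' covariate.

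Lists of other marrow cell types moved less or in both directions. In the NK cell list 6 of 17 fell, also when adjusted over the list alone (median -0.51, camera adjusted p = 0.00854, and 0.462 with an estimated correlation). Nkg7, which also stands in the neutrophil primary granule list, was at -2.99. Klrc1 stood at -1.44, Tbx21 at -1.08 and Gzmb at -0.84. With the beta-actin 3' to 5' difference as a covariate the calls of Klrc1, Tbx21 and Gzmb were lost (limma adjusted p of 0.194, 0.180 and 0.301). By fry the list had an adjusted p of 0.0528. The list's camera call was lost with that covariate (median -0.29, 0.114) and with genes of more than 1 list left out (-0.25, 0.0671). Its median was -0.34 without pool 2 and -0.28 with each array centred on its median, where the call stayed. The bright member Gzma did not pass at -1.29 (limma adjusted p = 0.0948) and did with the replicate block (0.0451), without sorted replicate 3 (0.000154) or without pool 3 (0.00197). In the megakaryocyte and platelet list 9 of 22 fell and 1 rose, and 10 fell when adjusted over the list alone (median -1.18, camera adjusted p = 0.00658; adjusted p = 0.462 with an estimated correlation), with Cd9 at -2.88 and Plek at -1.44, while Rap1b did not pass at -0.12, and the same covariate ended this call too (median -0.63, 0.0541). In the stem and progenitor cell list 11 of 30 fell and 5 rose, and 12 fell when adjusted over the list alone (median -0.31, camera adjusted p = 0.0379; adjusted p = 0.258 with an estimated correlation). Cd34, a surface marker of progenitors, stood at -3.51 and Tal1 at -3.09, while Myb and Sox4, its brightest members, rose by 1.10 and 2.72. The call of this list was lost without presort replicate 1, sorted replicate 2, pool 1 or pool 2 (adjusted p from 0.0554 to 0.0841). It was also lost with camera on ranks (0.0673) and without _x_at and _s_at probe sets (median -0.23, 0.0598). It was lost too without dim genes (0.0787) and without genes of more than 1 list (0.0872), where the median was further from 0, at -0.61 and -0.40. The median was nearer to 0 without pool 2, at -0.19, and with each array centred on its median, at -0.09 with the call kept. In the stromal and osteoblast list 7 of 22 fell, also when adjusted over the list alone (median -0.40, camera adjusted p = 0.0162; adjusted p = 0.419 with an estimated correlation), with the adhesion molecule gene Vcam1 at -2.62 (-1.68 with the covariate) and Col5a1 at -2.45. Its call was lost without sorted replicate 3 (adjusted p = 0.0559) or pool 3 (0.0520). It was lost without dim genes too (0.0772), where the median was further from 0, at -0.69, and with each array centred on its median it was -0.17 with the call kept.

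The T cell, dendritic cell, endothelial and osteoclast lists did not pass as groups. In the T cell list 1 of 18 members rose, the adhesion gene Cd2 at 3.24, and 2 fell, Cd28 at -0.72 and Lat at -0.57 (camera adjusted p = 0.456), with 1 rise and 0 falls when adjusted over the list alone. The Cd28 call was lost without presort replicate 1 or 3, sorted replicate 2 or any 1 pool (adjusted p from 0.0571 to 0.0799), the Lat call without any 1 presort array, sorted replicate 1 or 2, or pool 1 or 2 (0.0708 to 0.271), and without pool 3 the list itself passed at an adjusted p of 0.0240. With the beta-actin 3' to 5' covariate Cd28 stood at -0.82 ± 0.28 (SE; 0.0717) and Lat at -0.31 ± 0.20 (0.336), and neither passed with each array centred on its median (0.0951 and 0.106). The Cd28 call was also lost with the mean of its probe sets (0.123), and that of Lat with array weights (0.0718), an intensity trend (0.0533) or quantile normalization over genes (0.151). Zap70, a bright member, did not pass at -0.18. In the dendritic cell list 5 of 19 rose and 8 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.762), with Ly6d at 3.82, the chemokine receptor gene Ccr7 at 2.87, Spib, which B cells express too, at 2.27 and Cd209a at -1.74. In the endothelial list 7 of 22 fell and 1, Pecam1, rose by 1.29, with the same counts when adjusted over the list alone (camera adjusted p = 0.0790), and without presort replicate 1 or sorted replicate 2 this list passed (0.0401 and 0.0434), as it did with the mean of probe sets (0.0345), without genes of more than 1 list (0.0371) and by fry (0.0466). Eng, another bright member, stood at -0.68, a call lost without pool 3 (0.0849) and with the same covariate (-0.47 ± 0.17, SE; 0.0828), and -0.45 with quantile normalization over genes. Fabp4 stood at -2.37 (-1.32 with the mean of its probe sets) and Stab2 at -1.95. In the osteoclast list 1 of 11 members fell, Mmp9, which neutrophils share, also when adjusted over the list alone (camera adjusted p = 0.762), and Acp5 did not pass at 0.37 but did at 0.97 with the covariate (0.0369).

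No component of the renin-angiotensin system that was measured passed as higher with the processing used throughout, though Nln, Prep and Enpep did under other settings. Of 19 members 7 fell, also when adjusted over the list alone (camera adjusted p = 0.0446; adjusted p = 0.258 with an estimated correlation, 0.0507 with the replicate block, 0.0802 with camera on ranks). Agtr1a, the angiotensin receptor, stood at -3.37 ± 0.22 (SE; 10.3-fold lower, limma adjusted p = 2.75e-05). The other 6 that fell were the proteases and peptidases Ctsg at -2.91, Cpa3 at -2.82, Ctsd at -2.04, Rnpep at -1.40, Ctsb at -1.19 and Thop1 at -0.93 (-0.37 with the mean of its probe sets), of which Ctsg, Cpa3, Ctsb and Ctsd also stand in granulocyte, mast cell, macrophage or lysosome lists. With the beta-actin 3' to 5' covariate Ctsd stood at -1.33 and Ctsb at -0.69. The angiotensinogen gene Agt did not pass at -0.05 ± 0.13 (SE), nor did Ace at -0.07, Agtr1b at -0.01, Agtr2 at 0.01, Mas1 at -0.10, the prorenin receptor gene Atp6ap2 at -0.08, Mme at -0.02, Anpep at 0.06, Cma1 at 0.04, Nln at 0.63 or Prep at 0.29. Nln passed without presort replicate 3 (limma adjusted p = 0.0373), and at 0.85 with each array centred on its median (0.0433) or quantile normalization over genes (0.0463). Prep passed without sorted replicate 1 (0.0392), at 0.79 with the mean of its probe sets (0.00849) and at 0.91 with the beta-actin 3' to 5' covariate (0.0227). Enpep, the aminopeptidase that trims angiotensin, did not pass at 0.79 ± 0.37 (SE; adjusted p = 0.162) and did with the replicate block (0.0169), at 1.07 without pool 1 (0.00176) and at 1.25 without presort replicate 1 (0.00402). The list's call was lost without presort replicate 1, presort replicate 3, sorted replicate 3, pool 1 or pool 3 (adjusted p from 0.0541 to 0.0938), and its median of -0.07 was -0.93 without dim genes, with the call kept (0.0348), -0.02 without sorted replicate 1 and 0.15 with each array centred on its median. Without genes that stand in more than 1 list the median was -0.02 and the call was lost (0.445). Of the list of renin cell and smooth muscle genes 3 of 27 rose and 5 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.754). Acta2, smooth muscle actin, stood at -1.91, the adenylyl cyclase gene Adcy6 at -1.67 and Crip1 at -0.99, while the prostaglandin receptor gene Ptger4 rose by 1.87 and Crebbp by 0.72, and the bright member Gnas did not pass at 0.29. Gnas did pass at 1.95 without _x_at and _s_at probe sets (limma adjusted p = 0.000679) and at 0.66 with the mean of its probe sets (0.00636). Without _x_at and _s_at probe sets Acta2 stood at -0.28 and did not pass (0.150), and it stood at -0.70 with the mean of its probe sets and at -1.25 with the covariate. The Acta2 and Crebbp calls were lost without pool 3 (adjusted p of 0.0545 and 0.0575).

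Cell division genes were lower in sorted samples. All 29 measured G2 and M phase genes fell, also when adjusted over the list alone (camera adjusted p = 1.34e-19; adjusted p = 0.258 with an estimated correlation), among them the mitotic kinesin gene Kif20a at -3.18, Birc5 at -3.12, Ube2c at -3.02 and Tpx2 at -2.98 ± 0.19 (SE; -1.56 with the mean of its probe sets). Of the DNA replication list 34 of 36 fell and 1 rose, with the same counts when adjusted over the list alone (median -1.89, camera adjusted p = 2.70e-17; adjusted p = 0.258 with an estimated correlation), with the thymidine kinase gene Tk1 at -3.11, Cdc6 at -2.97 and Lig1 at -2.63. The G2 and M phase median was -2.92, -2.52 and -2.29 in pools 1, 2 and 3.

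Most immediate early genes were higher in sorted samples. Of 33 measured members of the immediate early and dissociation stress list, 20 rose and 1 fell, and 2 fell when adjusted over the list alone (median 1.30, camera adjusted p = 5.34e-06; adjusted p = 0.258 with an estimated correlation). Beside Fosb and Jun, the zinc finger genes Egr1 and Egr3 rose by 3.67 ± 0.94 and 3.32 ± 0.31 (SE), and Egr3 by 1.65 with the mean of its probe sets. The list's median was 0.84, 0.89 and 1.89 in pools 1, 2 and 3, and 0.85 without pool 3. Presort replicate 1 stood apart from the other presort arrays. Egr1 was at 11.78 there and at 8.59 and 7.42 in presort replicates 2 and 3. The 20 risers lay a mean of 1.21 ± 0.26 (SE over genes) higher there. The Egr1 call was lost without presort replicate 2, sorted replicate 3, pool 2 or pool 3 (adjusted p from 0.0563 to 0.128), and those of Jun and Egr1 with an intensity trend in the limma prior (0.0515 and 0.0686). With the beta-actin 3' to 5' difference as a covariate, a setting chosen after the control probe sets were seen, none of the 3 passed: Fosb stood at 4.32 ± 1.38, Jun at 4.43 ± 1.41 and Egr1 at 3.27 ± 1.35 (SE; adjusted p of 0.0592, 0.0579 and 0.125). The standard errors grew in each, while the difference of Jun did not shrink.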

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

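Except for the counts over other splits of the arrays, the tests in this part were chosen after the result was seen. The control probe sets, which the comparison of genes does not use, showed a larger 3' to 5' difference on each sorted array than on any presort array. For beta-actin it was 3.17, 1.54 and 1.43 in sorted replicates 1, 2 and 3, and for Gapdh 3.84, 2.13 and 2.44. Of 10092 probe sets without a single gene symbol, also outside the comparison, 641 rose and 305 fell at least 2-fold.

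B cell genes were higher in the sorted samples, and the loss of erythrocytes at the scatter gate alone would raise all other lineages together. The neutrophil, monocyte and macrophage list members had a median of -2.55 ± 0.17 (bootstrap SE over 98 genes, which leaves out the spread between arrays). This restates the falls of these lists given above, which argue against that loss as the only cause. Autofluorescent granulocytes and macrophages inside the gate would raise their own genes, and the 30 eosinophil and macrophage members had a median of -2.28 ± 0.31 (bootstrap SE over genes). This restates the falls of their lists given above and does not test a cause of the B cell rise. With the beta-actin 3' to 5' difference as a covariate the B cell list median was still 2.03 ± 0.10 (bootstrap SE over 23 genes). Of these genes 20 were called, and the erythroid list median with the covariate was -2.25 ± 0.37 (SE). The erythroid fall over pools 2 and 3 alone was -2.48 ± 0.36. Their sorted arrays also had larger 3' to 5' differences than every presort array, so this fall does not test 3' bias. The covariate differs between the groups too, so bias shared by all sorted arrays may stay in the adjusted values. They show that the rise and the fall remained after the adjustment, and cannot decide whether 3' bias was the whole cause. An enrichment of B lineage cells by the GFP gate is a hypothesis that may account for the rise and was not tested against cell counts. Each sorted sample passed the scatter, single-cell and GFP gates together, and presort samples were unsorted. The effects of these gates on the B cell rise and the erythroid fall therefore cannot be told apart here.

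Immediate early genes were higher in the sorted samples and also higher in presort replicate 1, which had no sorting. If they followed the share of B lineage cells, they would exceed the other presort arrays there by no more than B cell genes do. The excess of the 20 risers was 0.506 ± 0.276 (SE over genes) larger than that of the B cell list, within 2 standard errors. This SE does not measure the spread between arrays, and the 20 genes were called in a fit that includes presort replicate 1. If handling had raised a general stress response, heat shock genes might rise with them, and the median of Hspa1a, Hspa1b, Hspa8, Hsp90aa1 and Dnajb1 was 0.446 ± 0.511. The sorting time and the share of B lineage cells cannot be told apart here, because every sorted sample had both and 1 presort array carries the first test. That these genes are more active in the GFP-positive cells in the animal stays open and was not tested.

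RNA of other lineages was still measured in the sorted samples, with neutrophil RNA highest in sorted replicate 2. Carry-over of unsorted marrow at one share per array would move erythroid and neutrophil genes together. From pool 2 to pool 3 the sorted minus presort difference changed by 0.45 ± 0.09 in 27 erythroid genes. In 57 neutrophil genes it changed by -0.82 ± 0.12, and the changes lie 1.27 ± 0.15 (SE over genes) apart. From pool 1 to pool 2 the list medians moved the same way, from -3.08 to -2.57 for erythroid and from -2.88 to -1.96 for primary granule genes. Each pool has 1 presort and 1 sorted array, so the SE leaves out the spread between arrays. The gap therefore cannot decide on a single share. Carry-over at one share, carry-over of different cell types in different shares, and expression in the sorted cells stay open, and no test here parts them.

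The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For each of the counts of higher genes (2629), lower genes (3296), and genes at least 2-fold higher (1056) or lower (1872), 1 split of the 10, the real one, gave as many, and the highest of the other splits was 0 genes by limma, with up to 768 genes at an unadjusted p under 0.05 against 7283. Of the splits, 4 part all 3 pools, the real one included, and the highest of the others among them was 0 genes too. For the gene lists called, 1 split gave as many as the real 29, and the highest of the others called 23 lists with the preset correlation, among the splits that part all pools as well. Every other split sets 2 arrays of one group and 1 of the other against the reverse, so it still holds part of the sort difference, and its counts do not measure calls unrelated to the sort.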

How the results depend on the processing

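The covariate, fry and the normalization over named genes were chosen after the data were seen. Over all alternatives no list call changed direction, and of the named genes Ighm did, at -1.21 with the mean of its probe sets; of all 5925 called genes 3 were called the other way in that setting and 4 without _x_at and _s_at probe sets. Leaving out 1 array gave 1918 to 2608 higher and 2705 to 3256 lower genes, 975 to 1126 and 1806 to 1931 at least 2-fold, and 4 to 5 higher and 21 to 23 lower lists. Leaving out 1 pool gave 1544 (without pool 3) to 2400 and 2362 to 3222 genes, 970 to 1053 and 1819 to 1869 at least 2-fold, and 4 to 5 and 22 lists, with fewer samples; where 2 arrays of a group remain, limma pools the spread over genes. Median centring gave 5162 higher genes against 2629, by its own shift of every gene. treat, which tests against 2-fold itself, kept 362 higher and 1036 lower genes, and the estimated correlation 0 higher and 0 lower lists. The replicate block gave 2860 higher and 3548 lower genes, with 5787 of the 5925 calls kept, and among the lists ended only the renin-angiotensin call. With the 3' to 5' covariate 4275 of the 5925 calls were kept, with 2096 higher and 2732 lower genes; the cause was not tested. Quantile normalization over named genes put 54.3% of called genes higher. Calls of 9 lists were lost in some setting other than the estimated correlation: adhesion, megakaryocyte, NK cell, plasma cell, renin-angiotensin, ribosome biogenesis, stem and progenitor, stromal and interferon. Dim signal near background compresses folds, so small changes of dim genes are the least certain.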

Other observations

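The test of pro-B genes in this part was chosen after the result was seen. Of the list of complement, Fc and pattern recognition receptors 23 of 30 fell and 1 rose, with the same counts when adjusted over the list alone (median -1.70, camera adjusted p = 3.71e-09; adjusted p = 0.258 with an estimated correlation), with C5ar1, a receptor for a complement fragment, at -3.55 and Tlr13 at -3.47. Of the adhesion and migration list 14 of 25 fell and 5 rose, and 16 fell when adjusted over the list alone (median -1.42, camera adjusted p = 0.000783; adjusted p = 0.258 with an estimated correlation), with the chemokine receptor gene Ccr1 at -3.66, and without genes of more than 1 list its median was -0.44 and the call was lost (0.0981). Of the NADPH oxidase list 9 of 14 fell and 2 rose, with the same counts when adjusted over the list alone (median -0.91, -0.50 with the mean of probe sets, camera adjusted p = 0.00583; adjusted p = 0.258 with an estimated correlation), with Cybb, the oxidase's catalytic subunit, at -1.73 and Ncf1 at -1.38 (-2.19 with the mean of its probe sets). Of the lysosome list 13 of 28 fell and 1 rose, with the same counts when adjusted over the list alone (median -0.43, camera adjusted p = 0.00318; adjusted p = 0.258 with an estimated correlation), with Cd68 at -2.88, and its median was -0.21 with each array centred on its median. In the type I interferon list 16 of 28 fell and 6 rose, with the same counts when adjusted over the list alone (median -0.74, camera adjusted p = 0.0446; adjusted p = 0.462 with an estimated correlation), with Oas3 at -2.86 and Ifih1 at -2.45, and without presort replicate 2, presort replicate 3, sorted replicate 1 or pool 3 the call was lost (0.0507 to 0.0739). It was also lost with the beta-actin 3' to 5' covariate (median -0.40, 0.184), camera on ranks (0.0802), without dim genes (0.0890) and without genes of more than 1 list (0.0658). The inflammatory cytokine list did not pass (camera adjusted p = 0.135): 7 of 28 fell, 6 when adjusted over the list alone, and 1 rose in both, with the interleukin antagonist gene Il1rn at -3.63 (-1.94 with the mean of its probe sets) and Tnfaip3, an inhibitor of NF-kappaB signalling, at 3.21.

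Metabolic lists were lower or did not pass. Of the glycolysis list 14 of 18 fell, 15 with 1 rise when adjusted over the list alone (median -1.28, camera adjusted p = 2.48e-06; adjusted p = 0.263 with an estimated correlation), with Pfkfb4 at -3.05 and Hk3 at -2.86, and of the oxidative phosphorylation list 18 of 40 fell, 22 when adjusted over the list alone (median -0.52, camera adjusted p = 4.02e-05; adjusted p = 0.271 with an estimated correlation), with Sdhc at -1.56. The median of the latter list was -0.30 with the beta-actin 3' to 5' covariate and -0.29 with each array centred on its median. Of the ribosome biogenesis list 10 of 35 fell and 3 rose, and 14 fell when adjusted over the list alone (median -0.32, camera adjusted p = 0.0328; adjusted p = 0.462 with an estimated correlation), with the spermidine synthase gene Srm at -1.98, and without presort replicate 2, presort replicate 3, sorted replicate 2 or pool 2 the call was lost (0.0502 to 0.0886), as it was with the 3' to 5' covariate (median -0.16, 0.0913) and without dim genes (0.0890). Its median was -0.18 with quantile normalization over genes and -0.09 with median centring, where the call stayed. The cytosolic ribosome list did not pass (camera adjusted p = 0.762), with 2 of 29 members higher, 1 lower and the same counts when adjusted over the list alone, nor did cholesterol synthesis (0.141, 2 of 20 higher and 5 lower, the same counts when adjusted over the list alone; fry adjusted p = 0.00444), with Sqle at -1.55. The unfolded protein response list did not pass (camera adjusted p = 0.246), with 7 of 24 members higher and 4 lower, the same when adjusted over the list alone: Asns, the asparagine synthetase, stood at -3.18, while Syvn1 and Dnajb9 rose by 1.87 and 1.81. With the 3' to 5' covariate this list passed (median 0.38, 0.0308). The apoptosis and p53 target list did not pass (camera adjusted p = 0.604), with 5 of 22 higher and 3 lower, the same when adjusted over the list alone, with the death receptor gene Fas at -1.78 and Trp53inp1 at 1.27.

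Some genes of the earliest B lineage stages did not rise with the other B lineage genes. Dntt (-0.79, limma adjusted p = 0.0536, and 0.0431 with the replicate block) and Vpreb1 (-0.77, adjusted p = 0.103) did not pass, and Igll1 fell by 0.84. Other genes of the B cell progenitor list did rise, 14 of 18 with a list median of 1.47, among them Ebf1 by 3.06, Rag1 by 2.75, Sox4 by 2.72 and Il7r by 2.34. The mean of Dntt, Vpreb1 and Igll1 was -0.80 and that of the 23 B cell genes 2.00, a difference of -2.80. Since the 3 genes were picked after their values were seen, this difference cannot decide whether the sorted cells hold a smaller share of pro-B cells than the B lineage of whole marrow, and in pool 3 Igll1 stood at 0.00, Dntt at -0.04 and Vpreb1 at 0.14.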
